A study of Cynara cardunculus with 36 samples.

How the data were processed

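RNA from artichoke hearts of 4 cultivars at 3 days of cold storage was sequenced in 36 libraries, 3 per cultivar and day. Per the labels' protocols, the plants were grown in a field with GA treatment, the mature heads were kept in the cold before the first sampling, the hearts were frozen in liquid nitrogen, and total RNA was extracted with a plant RNA kit and treated with DNase. The labels call the replicates biological; p-values measure the spread between these libraries.

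The authors deposited 1 table per library with the count of reads for each of 28632 gene models, as whole numbers that were not normalized, and 5 summary rows for reads assigned to no gene model. Per the submitters' processing notes, cutadapt and STAR were used, with no version or role; the counting tool, the genome build, the annotation and the use of strand are not given in the sources used here. Reads shared by near-identical or overlapping gene models could therefore be split or dropped in a way that is not known, and the counts of such gene models are uncertain. The summary rows were left out of library sizes and tests. They held 13.9% to 85.2% of the reads listed per library (median 16.0%): reads outside gene models made up 9.39% to 71.0%, reads with more than 1 alignment 2.23% to 13.8% and ambiguous reads 0.385% to 2.99%.

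Groups and replicate numbers were taken from the sample titles. No 2 files were identical, and over 36 pairs of replicates the lowest chi-square per degree of freedom between the counts was 53.1, so no pair agreed within sampling noise and each library was counted as 1 replicate. Reads in gene models numbered 5.76 to 54.5 M per library. A gene model with 0 reads in the 12 day 0 libraries, which held 457 M reads in genes together, can lie up to 0.00656 CPM, from a floor of 3 counts over those libraries.

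The files name gene models by ID only. Of the 28632 IDs, 0 matched the NCBI RefSeq gene table of the assembly CcrdV1.1, which lists 30275 genes, so no gene names or positions are given. The 29 gene lists written as product names before the data were examined (browning enzymes, phenolic, lignin and flavonoid pathways, hormones, cell wall, cold response, senescence, sugar metabolism and others) could not be made, and their tests were not run. Under the rule fixed for this case, at most 2 IDs that rose and 2 that fell are named: those with the largest fitted log2 fold change at day 14 (mean of the 4 cultivars) among gene models with adjusted p under 0.05, a mean log2 CPM of at least 1 and the same sign of change in all 4 cultivars. That they were taken at day 14 was settled after the data were seen.

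Counts were analysed with edgeR 4.0.16 (limma 3.58.1) in R 4.3.3. Numbers of reads marked M are in the unit of the M in CPM. Gene models were kept by filterByExpr over the 12 groups (minimum count 10, minimum total count 15), which left 21900. Libraries were scaled by TMM, dispersions were estimated with estimateDisp (biological coefficient of variation 0.506), and glmQLFit with robust estimation and glmQLFTest were applied to 1 fit of all 36 libraries with a mean for each cultivar and day. A gene model was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were each later day against day 0 as the mean of the 4 cultivars and within each cultivar, day 14 against day 7, the difference between cultivars in the change from day 0 (F test, 3 degrees of freedom), the cultivars at day 0 (F test) and each cultivar against the mean of the others at day 0. Standard errors are the absolute log2 fold change divided by the square root of F. CPM were computed here from the deposited counts with TMM scaling; principal components used log2 CPM with a prior count of 2. Counting intervals are 95% Clopper-Pearson intervals.

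The fit was tested on simulated counts for 21900 gene models drawn from the means, dispersions and depths of these libraries, with 100 gene models changed 2-fold and 100 changed 4-fold per comparison. The changed gene models were taken from those with a mean log2 CPM over 0. Few gene models changed and no library was made to stand apart. The simulation therefore does not test the scaling under broad changes or the effect of deviating libraries. For day 14 against day 0 averaged over the cultivars, 59 of the 2-fold and 92 of the 4-fold changes were recovered. Its 181 calls also include gene models changed at day 14 in OP alone, and 18 were of gene models with no day 14 change. Within OP at day 14, 5 and 51 were recovered. For the difference between cultivars at day 14, 0 and 21 were recovered, and 3 of its 24 calls were of gene models with no such difference. For the F test at day 0, 9 and 58 were recovered, and for OP against the others at day 0, 21 and 76.

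Cultivar markers were chosen on the day 0 libraries alone, at under 0.1 CPM in one state and over 1 CPM in the other, in CPM without TMM scaling, and read in later libraries as on above 0.316 CPM. For counts of gene models detected at equal depth, every library was thinned at random to the smallest library, 5.76 M reads in genes. Alternatives written before the data were examined were size factors by the RLE method in place of TMM, DESeq2 1.42.0 (Wald and likelihood ratio tests), no filter on low counts, a log2 fold change over 1 as well, the replicate number as a block, fits of only the libraries compared, and each library left out in turn. Chosen after seeing the data were fits without the 4 libraries high in reads outside genes (over 25%), without the 2 day 14 libraries with crossed cultivar markers, and without all 6. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.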

Results

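RNA was sequenced from the hearts of globe artichoke heads (Cynara cardunculus var. scolymus), the inner part of the head that is eaten, after harvest and storage in the cold. The stated aim was to find genes involved in the fast ageing and loss of quality of the harvested head. The hearts came from 4 cultivars, Opal (OP), Imperial Star (IS), Green Globe Improved (GGI) and Green Queen (GQ). They were sampled at day 0, day 7 and day 14 of storage, with 3 biological replicates per cultivar and day, or 36 libraries in 12 groups. Reads assigned to gene models numbered 5.76 to 54.5 M (mega, as in the M of CPM) per library, with a median of 39.6 M. Library numbers ran from 1 to 12 at day 0, from 13 to 24 at day 14 and from 25 to 36 at day 7, so that the order of the libraries and the day of storage cannot be told apart.

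Some libraries stood apart from the rest of their groups. Reads outside the gene models made up 9.39% to 16.0% of the reads listed in 32 libraries, and 71.0% in OP day 7 replicate 1, 33.5% in GGI day 7 replicate 2, 31.6% in GQ day 7 replicate 2 and 30.1% in GQ day 7 replicate 3. The OP library also held the fewest reads in genes, 5.76 M. At day 14, the library labelled GGI replicate 1 and the library labelled GQ replicate 1 each showed the marker states of the other cultivar. Of 31 gene models that were on in all libraries of one of these cultivars and off in all libraries of the other at day 0, 31 were in the GQ state in the library labelled GGI and 26 were in the GGI state in the library labelled GQ. All libraries were kept in their labelled groups, and counts without the doubtful libraries are given where they differ by over 1.5 times.

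**Figure D1:**
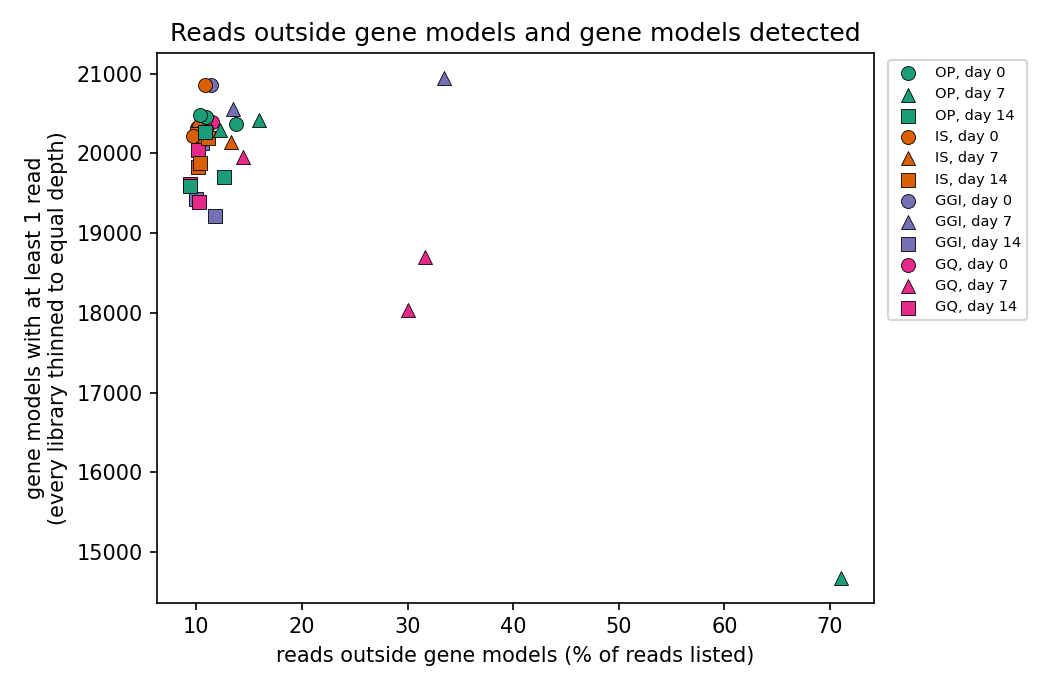
Gene models with at least 1 read, after every library was thinned to 5.76 M reads in genes (y axis), against reads outside gene models as a percentage of the reads listed (x axis), 1 point per library, coloured by cultivar and shaped by day. The 4 libraries above 30% are all from day 7; 3 of them detect 14682 to 18702 gene models, and the GGI library detects 20945, against 19209 to 20863 in the other 32.

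**Figure D2:**
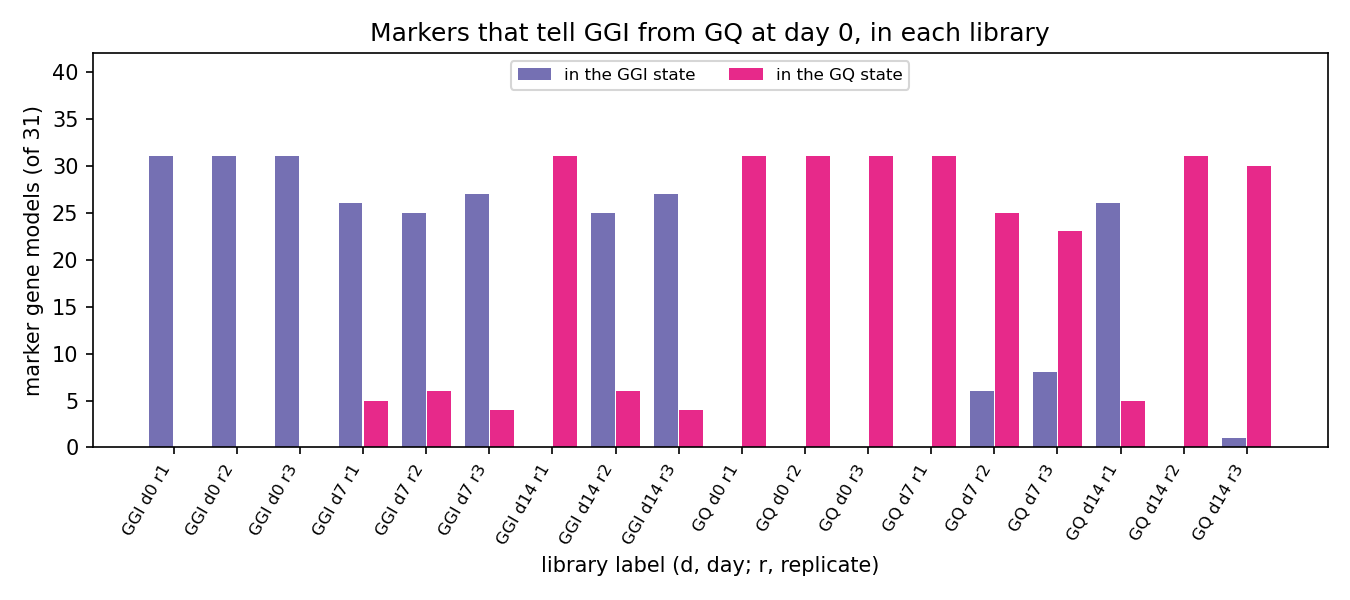
Number of the 31 marker gene models in the GGI state and in the GQ state (y axis) in each library labelled GGI or GQ (x axis, by day and replicate); the markers were chosen on the day 0 libraries. The libraries labelled GGI day 14 replicate 1 (0 in the GGI state) and GQ day 14 replicate 1 (26 in the GGI state) show the states of the other cultivar.

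The day 14 libraries separated from the others along the first principal component of log2 CPM, which held 32.9% of the variance. Day 0 libraries lay between -149 and -43.8, day 7 libraries between -116 and 33.9 and day 14 libraries between 70.4 and 221. Of the 12 day 7 libraries, 8 lay within the day 0 range. The second component held 18.4% and set apart OP day 7 replicate 1, GQ day 7 replicate 3 and GQ day 7 replicate 2, at 413, 195 and 132.

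**Figure D3:**
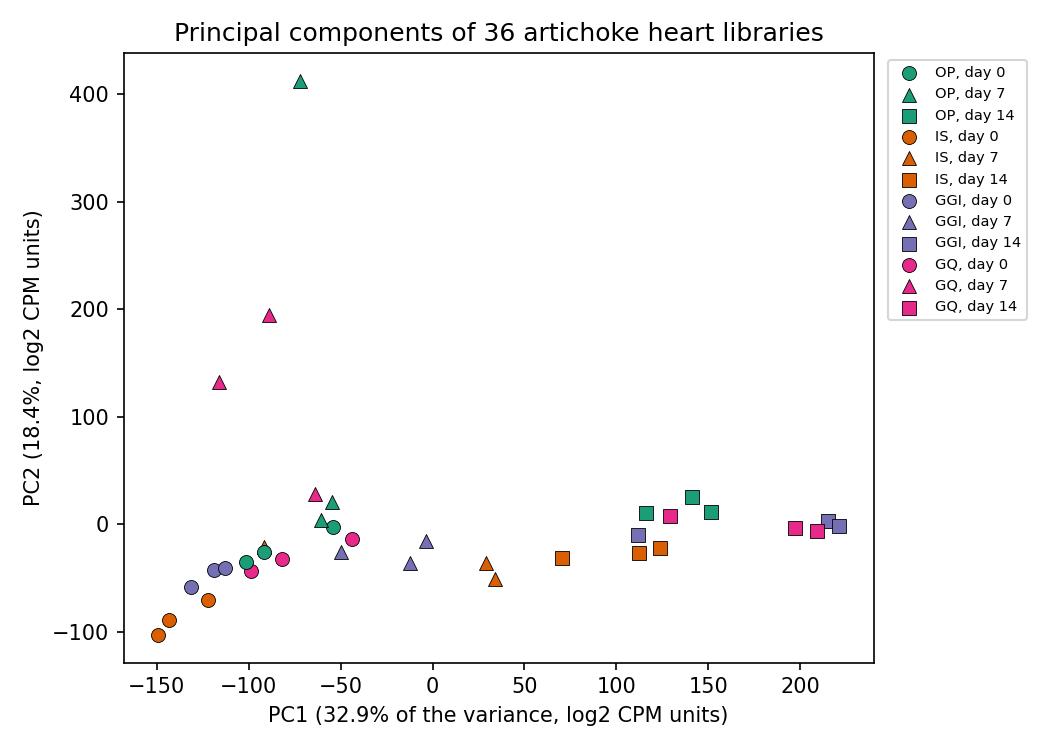
First and second principal components of log2 CPM over 21900 gene models, 1 point per library, coloured by cultivar and shaped by day. The 12 day 14 libraries lie at 70.4 or above on the first component, and 3 day 7 libraries of OP and GQ lie at 132 or above on the second.

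The comparison of day 14 with day 0, averaged over the cultivars, asked which gene models changed over the full storage time. Candidates were called gene models with a mean log2 CPM of at least 1 and the same sign of change in all 4 cultivars. Among these, V2_16g006270.1.01 and V2_04g002880.1.01 had the largest fitted rises, and V2_10g009860.1.01 and V2_03g016050.1.01 the largest fitted falls. This order rests on fitted values, which are uncertain where a group holds 0 reads. V2_16g006270.1.01 rose from 1 read in 457 M over the 12 day 0 libraries to 402 ± 340 CPM (SD, n = 12) at day 14, with values from 109 to 1247 CPM, a ratio of 154340 with a 95% Clopper-Pearson counting interval of 27701 to 6096300 (edgeR quasi-likelihood test, adjusted p = 2.1e-12). V2_04g002880.1.01 had 0 reads at day 0, which allows up to 0.00656 CPM, and was at least 79245-fold higher at day 14 against a floor of 3 counts over the day 0 libraries (adjusted p = 1.64e-06). The 95% Clopper-Pearson counting interval of V2_04g002880.1.01 began at 64446-fold. Its day 14 level was uneven, at 653 ± 1340 CPM (SD, n = 12) and from 0.541 to 3547 CPM. Of its 269949 day 14 reads, 138417 lay in the library labelled GQ replicate 1. V2_10g009860.1.01 fell from 38.7 ± 33.7 to 0.0657 ± 0.180 CPM (SD, n = 12 per day; adjusted p = 9.01e-09), with 32 reads left in all day 14 libraries together. V2_03g016050.1.01 fell from 534 ± 617 to 1.27 ± 3.92 CPM (SD, n = 12 per day; adjusted p = 1.11e-09). Intervals and floors cover counting error only. Fitted fold changes at day 14 are not given for V2_16g006270.1.01, V2_04g002880.1.01 and V2_10g009860.1.01, because some of their groups hold 0 reads in every library. For V2_03g016050.1.01, every group held reads, though only 3 in GQ at day 14. Its log2 fold change was -10.7 ± 1.03 (SE).

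In all, 13044 of the 21900 gene models tested, or 59.6%, were called at day 14 (adjusted p under 0.05), 6662 higher and 6382 lower. Of these, 8282 changed by over 2-fold, 3900 higher and 4382 lower, and 1519 by over 16-fold. The median change of a called gene model was 2.53-fold. Scaling by size factors in place of TMM shifted the median change of all gene models by -0.109 on the log2 scale (by -0.149 in IS and -0.118 in GGI), and the changes given are relative to TMM. The balance of calls turned, to 5934 higher and 7195 lower under RLE scaling and 6307 higher and 7660 lower with DESeq2.

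**Figure D4:**
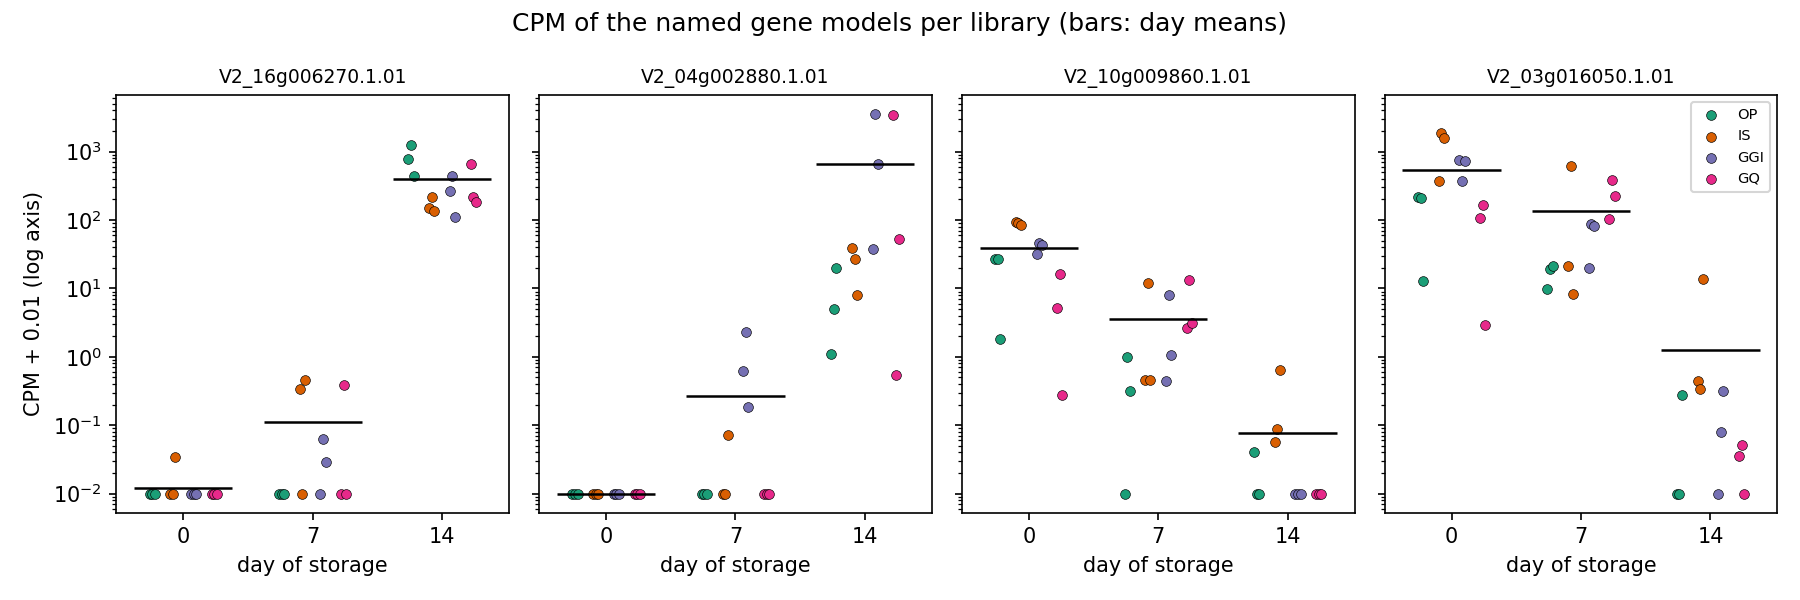
CPM + 0.01 on a log axis (y axis) of the 4 named gene models by day of storage (x axis), 1 point per library, coloured by cultivar; horizontal bars are day means over 12 libraries, and libraries with 0 reads lie at the bottom of the axis. V2_16g006270.1.01 lies at 109 CPM or above in every day 14 library and V2_10g009860.1.01 at 0.633 CPM or below.

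Within cultivars, V2_16g006270.1.01 reached 818 ± 408 CPM in OP, 167 ± 42.5 in IS, 268 ± 162 in GGI and 355 ± 266 in GQ at day 14 (SD, n = 3 each). It was called in each cultivar, with adjusted p from 7.24e-07 to 2.1e-06 (edgeR). V2_04g002880.1.01 was at 8.57 ± 9.80 CPM in OP and 24.5 ± 15.4 in IS, and at 1412 ± 1874 in GGI and 1166 ± 1974 in GQ (SD, n = 3 each). For V2_04g002880.1.01, the library labelled GQ replicate 1 held 3445 CPM against 0.541 and 53.1 in the other GQ libraries. For the same gene model, the library labelled GGI replicate 1 held 37.1 CPM against 3547 and 652 in the other GGI libraries. These are the libraries whose cultivar markers were crossed. V2_03g016050.1.01 fell in IS from 1285 ± 809 to 4.82 ± 7.70 CPM (SD, n = 3 each; edgeR, adjusted p = 0.00107) and in OP from 146 ± 116 to 0.0903 ± 0.156 CPM (adjusted p = 0.000426). The test of a difference between cultivars in the day 14 change did not call V2_10g009860.1.01 (edgeR, adjusted p = 0.790) or V2_03g016050.1.01 (adjusted p = 0.591). It is not given for the gene models that rose, which had 1 read and 0 reads at day 0.

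At day 14, 5655 gene models were called in OP (3085 higher, 2570 lower), 7161 in IS (3757 higher, 3404 lower), 8569 in GGI (4611 higher, 3958 lower) and 6619 in GQ (3629 higher, 2990 lower). A common set of 2704 gene models was called in the same direction in all 4 cultivars, 1580 higher and 1124 lower, where 18.5 and 9.86 would fall together if the cultivars were independent. The balance of the common set depended on the method, with 1400 higher and 1332 lower under RLE scaling and 1679 higher and 1857 lower with DESeq2. Within cultivars, RLE scaling gave more lower than higher calls in OP, IS (3215 higher, 4060 lower) and GGI, but not in GQ (3368 higher, 3262 lower). DESeq2 gave more lower calls in all 4 cultivars, with 3725 higher and 5013 lower in IS. By contrast, 167 gene models were called in opposite directions in different cultivars. The log2 fold changes of 2 cultivars correlated across gene models with r from 0.661 for IS and GQ to 0.792 for GGI and GQ; gene models are not independent replicates. Without the 6 libraries that stood apart, which include the GGI and GQ libraries with crossed markers, r was 0.732 for GGI and GQ and 0.640 to 0.764 over all pairs. Without the 4 libraries high in reads outside genes, which enter the shared estimate of the spread, the counts were 9768 in OP, 11346 in IS and 10544 in GQ, and 4765 in the common set. Fitted to each cultivar's own libraries, OP had 3752, GQ 3928 and the common set 1757, and OP had 3493 without its day 14 replicate 2.

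**Figure D5:**
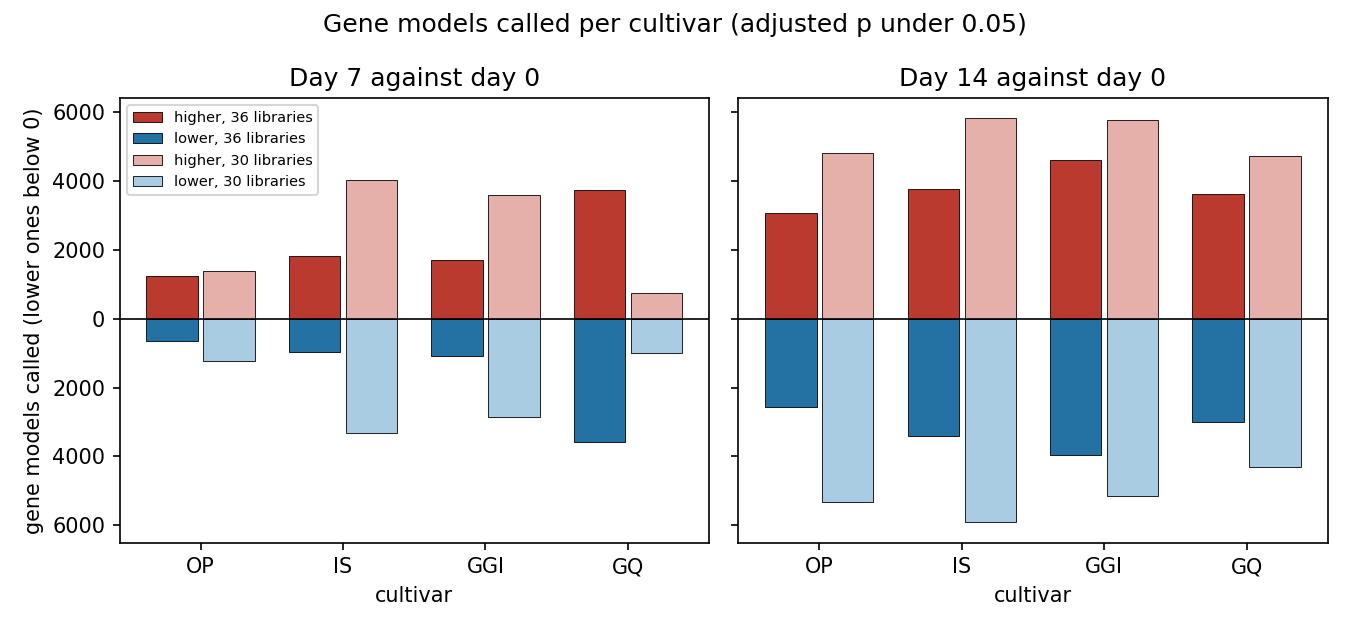
Gene models called higher (above 0) and lower (below 0) than at day 0 (y axis) in each cultivar (x axis) at day 7 (left) and day 14 (right), in the fit of all 36 libraries (dark) and of the 30 libraries left without the 6 that stood apart (light). In GQ at day 7 the calls fall from 7331 to 1724, and in IS they rise from 2789 to 7344.

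The comparison of day 7 with day 0 asked what had changed in the first week of storage. V2_10g009860.1.01 had fallen from 38.7 ± 33.7 to 3.56 ± 4.77 CPM (SD, n = 12 per day), a log2 fold change of -3.32 ± 0.68 (SE; edgeR, adjusted p = 0.000535). In GQ, V2_10g009860.1.01 was at 7.13 ± 8.07 CPM at day 0 and at 6.38 ± 6.04 CPM at day 7 (SD, n = 3 each; edgeR, adjusted p = 0.944), and the change in GGI did not pass either (adjusted p = 0.0749). V2_03g016050.1.01 had fallen from 534 ± 617 to 133 ± 189 CPM (SD, n = 12 per day), a log2 fold change of -1.89 ± 0.67 (SE; edgeR, adjusted p = 0.0266). In GQ, V2_03g016050.1.01 was at 91.0 ± 81.8 CPM at day 0 and at 238 ± 141 CPM at day 7 (SD, n = 3 each), a difference that did not pass the test (edgeR, adjusted p = 0.435). The call of V2_03g016050.1.01 was lost without the 4 libraries high in reads outside genes (edgeR, adjusted p = 0.0650) and without GQ day 0 replicate 2 (adjusted p = 0.0521), in a range of 0.00107 to 0.0738 over all alternatives. The log2 fold change of V2_03g016050.1.01 in these fits was -2.24 and -1.72. Its call was also lost with the replicate number as a block (edgeR, adjusted p = 0.0627), at a log2 fold change of -1.93. V2_16g006270.1.01 had 53 reads and V2_04g002880.1.01 had 132 reads over the 12 day 7 libraries. Of the 132 reads, 129 lay in GGI, and 88 of them in GGI day 7 replicate 2, which is high in reads outside genes. Against day 0, V2_16g006270.1.01 was higher by a ratio of 50.8 (95% Clopper-Pearson counting interval 8.74 to 2045). Pooled over the cultivars, V2_04g002880.1.01 was at least 42.2-fold higher against the floor of 3 counts, a bound that rests mostly on that GGI library. The edgeR test of the mean could not decide on either, with standard errors of 10590 for V2_16g006270.1.01 and 29430 for V2_04g002880.1.01, because OP, and for V2_04g002880.1.01 also GQ, had 0 reads on both days. Within IS, V2_16g006270.1.01 had an adjusted p of 0.0557, and within GGI, V2_04g002880.1.01 had 0.160 (edgeR). DESeq2 called both, with adjusted p of 0.00262 for V2_16g006270.1.01, in a range of 0.00262 to 1 over the alternatives, and 1.93e-09 for V2_04g002880.1.01, in a range of 1.93e-09 to 1.

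On average over the cultivars, 8229 gene models were called at day 7, 4377 higher and 3852 lower, 3933 of them by over 2-fold. The median change of a called gene model was 1.95-fold. For this mean the balance turned, to 4176 higher and 4292 lower under RLE scaling and 4760 and 5048 with DESeq2. It also turned to more lower calls without the 4 libraries high in reads outside genes, and part of the calls was lost. The median absolute log2 fold change of a called gene model was then 0.756, against 0.966 with all libraries. By cultivar, 1881 were called in OP (1243 higher, 638 lower), 2789 in IS (1820 higher, 969 lower), 2779 in GGI (1701 higher, 1078 lower) and 7331 in GQ (3742 higher, 3589 lower). DESeq2 gave a more even balance in OP (2036 higher, 1503 lower), IS (2296 higher, 2149 lower) and GGI (2435 higher, 2078 lower). Without the 4 libraries, part of the OP calls was lost and the balance in OP was also more even. The median absolute log2 fold change of the OP calls was then 1.12, against 2.02 with all libraries. The set called in the same direction in all 4 cultivars held 105 gene models, 95 higher and 10 lower, where 1.37 and 0.228 would fall together if the cultivars were independent, and 580 were called in opposite directions in different cultivars. Fold changes correlated across gene models with r = 0.526 between IS and GGI and with r from 0.0702 to 0.384 between the other pairs. The highest of these, for OP and GQ, was 0.256 without the 6 libraries that stood apart; the OP library high in reads outside genes and both such GQ libraries deviated from their groups together, with r of 0.527 and 0.520 across gene models. Without the 4 libraries high in reads outside genes, GQ had 1619 calls, IS 6900 and GGI 5965; GQ is then left with 1 day 7 library, which is assumed to vary like the other groups. With DESeq2 the counts were 3539 in OP, 4445 in IS, 4513 in GGI and 222 in all 4 cultivars, and fitted to each cultivar's own libraries 283 in OP, 5965 in IS, 3358 in GQ and 31 in all 4. The replicate number as a block gave 729 in OP and 56 in all 4. With 1 library left out, the counts ran from 450 to 2410 in OP, where each day 0 library and day 7 replicate 1 moved the count by over 1.5 times. They ran from 1318 to 3624 in IS (day 0 replicates 2 and 3, day 7 replicates 1 and 3), from 1321 to 1987 in GGI (all but day 7 replicate 2). They ran from 4268 to 10787 in GQ (day 7 replicates 2 and 3) and from 44 to 157 in all 4 cultivars (OP day 0 replicates 1 and 2, each GGI day 0 library and GGI day 7 replicate 1).

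The comparison of day 14 with day 7 covered the later part of storage, and all 4 named gene models were called in it. V2_16g006270.1.01 rose from 0.103 ± 0.174 to 402 ± 340 CPM (SD, n = 12 per day; edgeR, adjusted p = 3.94e-11) and V2_04g002880.1.01 from 0.261 ± 0.665 to 653 ± 1340 CPM (adjusted p = 7.44e-06). V2_10g009860.1.01 fell from 3.56 ± 4.77 to 0.0657 ± 0.180 CPM (edgeR, adjusted p = 3.36e-06) and V2_03g016050.1.01 from 133 ± 189 to 1.27 ± 3.92 CPM (adjusted p = 3.15e-08). In all, 12599 gene models were called between these days, 6389 higher and 6210 lower at day 14, and 7564 differed by over 2-fold. Here too the balance turned, to 5877 higher and 6733 lower under RLE scaling and 6292 higher and 7266 lower with DESeq2.

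Whether the cultivars differed in their change was tested for each gene model with an F test with 3 degrees of freedom. At day 7, 5325 gene models were called, or 24.3% of those tested, and at day 14, 691, or 3.16%. At day 7 the adjusted p was 0.168 for V2_03g016050.1.01 and 0.152 for V2_10g009860.1.01 (edgeR). Without the 4 libraries high in reads outside genes the counts were 4643 at day 7, of which 2924 were among the 5325, and 4292 at day 14. Over these fits the days thus did not keep their difference in count. Without all 6 that stood apart, the day 14 count was 3571, of which 680 were among the 691. With DESeq2 the counts were 8463 at day 7 and 2202 at day 14, and in fits of the days compared alone 2950 and 4554. The replicate number as a block gave 3535 and 279. Leaving out 1 library took the day 7 count as high as 9833 (without GQ day 7 replicate 1) and as low as 3421 (without GQ day 0 replicate 3). The day 14 count lay between 351 and 1273. It moved by over 1.5 times without each of IS day 0 replicates 2 and 3, GGI day 0 replicate 1, GQ day 0 replicates 1 and 3, the IS day 14 libraries and GGI day 14 replicate 3.

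The cultivars were also compared at the first sampling, before which the heads had already been kept in the cold. At day 0, 84 gene models were on (over 1 CPM) in all libraries of one cultivar and off (under 0.1 CPM) in all libraries of the other cultivars, or the reverse. IS had 40 of these, 11 on only in IS and 29 off only in IS; GGI had 18 (10 on, 8 off), OP 13 (4 on, 9 off) and GQ 13 (10 on, 3 off). Random splits of the 12 libraries into 4 groups of 3 gave 1.58 such gene models on average over 100 splits and at most 40. The splits could keep the 3 libraries of a cultivar together, and 40 is also the number in IS. The highest count is therefore not a measure of chance alone, and the split behind it was not examined.

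The F test between the cultivars at day 0 called 3125 gene models, or 14.3%. Against the mean of the other cultivars, 518 were called in OP (392 higher, 126 lower), 2603 in IS (1349 higher, 1254 lower), 833 in GGI (598 higher, 235 lower) and 1238 in GQ (977 higher, 261 lower). V2_03g016050.1.01 and V2_10g009860.1.01 did not pass the F test at day 0 (edgeR, adjusted p = 0.134 and 0.190), and the other named gene models held too few reads at day 0 to be tested. With DESeq2 the balance of higher and lower calls was more even in OP (482 higher, 379 lower), GGI (857 higher, 669 lower) and GQ (1163 higher, 990 lower). In a fit of the day 0 libraries alone the F test called 10085 gene models, and without the 4 day 7 libraries high in reads outside genes 8508. The counts against the other cultivars without those 4 libraries were 1296 in OP, 6652 in IS, 3380 in GGI and 3841 in GQ. Leaving out 1 library moved the counts to as few as 1944 for the F test (IS replicates 2 and 3), 195 in OP (replicates 1 and 3), 1090 in IS (replicates 2 and 3), 387 in GGI (any of its replicates) and 431 in GQ (replicates 1 and 3).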

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

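The tests of explanations for the libraries high in reads outside gene models and for the crossed cultivar markers were chosen after the result was seen, as were the fits without these libraries; the counts of random splits were planned.

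The cultivars differed in their change from day 0 by the F test in 5325 gene models at day 7 and in 691 at day 14 (edgeR). Among 100 splits that exchanged the day 7 libraries between cultivars and left day 0 in place, 4 called as many gene models as the real one, counting the real one. Such splits also mix cultivars that already differed at day 0. They therefore cannot decide whether a difference in change arose by chance, and chance is excluded at neither day. Fitted to these days alone, the real split called 2950, the highest other 8211 and the median other 174. At day 14, 10 of 100 such splits called as many, with 4554 for the real split, 6599 for the highest other and 2167 for the median other. The real day 14 split holds the GGI and GQ libraries with crossed markers, and the day 7 splits hold the libraries high in reads outside genes. The splits were not rerun without them, and what lies behind the counts above the real one was not tested.

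Reads outside gene models, which enter no comparison, made up 71.04% of the reads listed in OP day 7 replicate 1, 33.47% in GGI day 7 replicate 2, 31.61% in GQ day 7 replicate 2 and 30.06% in GQ day 7 replicate 3, against at most 16.0% in the other 32 libraries. In the OP and GQ libraries, genomic DNA was argued against, because all 3 detected fewer gene models at equal depth than the lowest of the other 32 (19209). Lower depth was argued against too, since 14682, 18702 and 18039 gene models remained after thinning against 19958 to 20557 in the other 8 day 7 libraries. Dilution alone was argued against as well. The root mean square log2 CPM distance to a groupmate outside the 4 was at least 1.29, against at most 1.11 in 5 pairs with none of the 4. The GQ libraries among the 4 lay 0.889 from each other. For the GGI library, dilution by reads from outside the genes may be enough, with a lowest distance of 0.930, and genomic DNA cannot be told apart from chance, because its 20945 detected gene models lie above the highest of the other 32 (20863) while its 41 otherwise silent gene models lie below the 58 reached when 1 of the 32 is set against the rest. What set the OP and GQ libraries apart stays open, and neither RNA quality nor a biological difference between heads was tested.

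In the library labelled GGI day 14 replicate 1, 31 of 31 markers that tell GGI from GQ were in the GQ state, and in the library labelled GQ day 14 replicate 1, 26 of 31 were in the GGI state. A change of the markers with storage was argued against by the other 4 day 14 libraries of GGI and GQ, which held at least 25 of 31 in the state of their own label. A mixture of both cultivars was argued against because 0 of the markers on only in the labelled cultivar were on in either library. Exchanged labels are a candidate explanation, with at least 26 markers in the other state in each of both libraries, and no record of the samples was used to test it. Both libraries were kept under their labels.

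For the other counts beyond those within 1 cultivar, splits were fitted to all cultivars on the days compared. In each case 1 of 100 splits, the real one itself, called as many gene models. This argues against chance for the mean of the cultivars, for calls in all 4 cultivars and for the F test at day 0. For the mean of the cultivars, the real count and the highest other were 7181 and 1932 at day 7, 15613 and 9988 at day 14, and 11001 and 4998 between day 7 and day 14. For gene models called in the same direction in all 4 cultivars they were 64 and 0 at day 7 and 4915 and 0 at day 14, where fits of each cultivar's own libraries gave 31 and 1757. At day 0 they were 10085 and 3254 for the F test. For 1 cultivar against the others they were 2270 and 1756 for OP, 8100 and 4993 for IS, 4667 and 4334 for GGI and 5531 and 2227 for GQ. The day 0 splits mixed the libraries of all 4 cultivars. They therefore cannot decide whether 1 given cultivar differs from the rest. Within 1 cultivar, fitted to its own libraries, 10 splits are too few for a share under 0.05. There the highest other count was 0 throughout, against 283 in OP, 5965 in IS, 3842 in GGI and 3358 in GQ at day 7 and 3752, 10562, 9178 and 3928 at day 14.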

How the results depend on the processing

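The fits without 4 libraries high in reads outside genes, without the 2 libraries with crossed markers and without all 6 were chosen after seeing the data; the other alternatives were planned. All 20 counts of called gene models stayed within 1.5 times under RLE scaling, with no low-count filter and without the 2 crossed libraries. The balance of higher and lower calls did move, for the mean at day 14 from 51.1% higher to 45.2% under RLE scaling. The day 14 falls and rises of the 4 named gene models kept direction and call under every alternative run. Unless a reason is given, the cause was not tested.

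With a log2 fold change over 1 required as well, which can only lower a count, 3933 gene models were called for the mean at day 7, 8282 at day 14 and 7564 between day 7 and day 14. With DESeq2 the counts were 3539 in OP, 4445 in IS and 4513 in GGI at day 7, 222 in all 4 cultivars at day 7 and 8463 and 2202 for the difference between cultivars at day 7 and day 14. At day 0 DESeq2 gave 4932 for the F test, 861 for OP, 4000 for IS, 1526 for GGI and 2153 for GQ. Fitted to fewer libraries, so with their own estimate of the spread (each cultivar's own libraries within cultivars, the days compared for the difference between cultivars, day 0 alone for day 0), they were 283 in OP, 5965 in IS and 3358 in GQ at day 7, 3752 in OP and 3928 in GQ at day 14, 31 and 1757 in all 4 cultivars at day 7 and day 14, 2950 and 4554 for the difference between cultivars. At day 0 such fits gave 10085 for the F test, 2270 for OP, 8100 for IS, 4667 for GGI and 5531 for GQ.

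Without the 4 libraries, the counts were 6900 in IS, 5965 in GGI and 1619 in GQ at day 7, 9768 in OP, 11346 in IS and 10544 in GQ at day 14, 4765 in all 4 cultivars at day 14, 4292 for the difference between cultivars at day 14. At day 0 they were 8508 for the F test, 1296 for OP, 6652 for IS, 3380 for GGI and 3841 for GQ. Without all 6 they were 7344 in IS, 6440 in GGI and 1724 in GQ at day 7, 10149 in OP and 11743 in IS at day 14, 4393 in all 4 cultivars at day 14, 3571 for the difference at day 14. At day 0 they were 9060, 1566, 7107, 3777 and 4294 in the same order. Of the 7331 calls in GQ at day 7, 1437 were among those 1724, with 1 GQ day 7 library left and assumed to vary like the other groups. Of the 13044 calls for the mean at day 14, 12884 were among the 15467 called without the 6.

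With the replicate number as a block, the counts were 729 in OP at day 7, 56 in all 4 cultivars at day 7, and 3535 and 279 for the difference between cultivars at day 7 and day 14. The replicate numbers did not meet the rule that every pair must lie over 0.1. A partial pairing can miss this rule too and is not excluded. Of 36 pairs of equal number, 9 had deviations correlated across gene models with r over 0.1 (-0.336 to 0.321), and 17 of 36 libraries were closest to their own number. At day 0, 5 of 18 pairs across cultivars lay over 0.1 (-0.258 to 0.634), the highest for OP and GQ replicate 3. The fall of V2_03g016050.1.01 at day 7 was not called with the block (adjusted p = 0.0627), without the 4 libraries (0.0650), without the 6 (0.0738) or without GQ day 0 replicate 2 (0.0521), in a range of 0.00107 to 0.0738 (edgeR and DESeq2). Its log2 fold change was -1.93, -2.24, -2.22 and -1.72 in these fits, against -1.89. The block changed no other call of a named gene model.

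With 1 library left out, 44 of the refitted counts moved by over 1.5 times and 232 did not. The lowest and highest were 450 and 2410 in OP, 1318 and 3624 in IS, 1321 and 1987 in GGI and 4268 and 10787 in GQ at day 7, 3493 and 5058 in OP at day 14, 44 and 157 in all 4 cultivars at day 7, 3421 and 9833 for the difference between cultivars at day 7 and 351 and 1273 at day 14. At day 0 they were 1944 and 2796 for the F test, 195 and 514 for OP, 1090 and 2639 for IS, 387 and 741 for GGI and 431 and 1242 for GQ. The libraries behind the moves within storage were OP day 0 replicates 1, 2 and 3 and day 7 replicate 1 (OP at day 7), OP day 14 replicate 2 (OP at day 14), IS day 0 replicates 2 and 3 and day 7 replicates 1 and 3 (IS) and the GGI day 0 libraries and GGI day 7 replicates 1 and 3 (GGI). They were also GQ day 7 replicates 2 and 3 (GQ), OP day 0 replicates 1 and 2, the GGI day 0 libraries and GGI day 7 replicate 1 (all 4 cultivars), GQ day 0 replicate 3 and day 7 replicate 1 (difference at day 7). The difference at day 14 moved without IS day 0 replicates 2 and 3, GGI day 0 replicate 1, GQ day 0 replicates 1 and 3, the IS day 14 libraries and GGI day 14 replicate 3. At day 0 they were IS replicates 2 and 3 (F test and IS), OP replicates 1 and 3, GGI replicates 1, 2 and 3, and GQ replicates 1 and 3.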

Other observations

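The tests of position along the storage axis, of the GGI markers and of on and off gene models were chosen after the result was seen; the test of neighbouring gene models was written before its result.

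At day 14, 10 gene models were off (under 0.1 CPM) in all 12 day 0 libraries and on (over 1 CPM) in all 12 day 14 libraries, V2_16g006270.1.01 among them, and 1 did the reverse. At day 7 there were 0 and 0. Random splits of the same libraries gave 0 in each of 100 splits, and without the 6 doubtful libraries the counts at day 14 were again 10 and 1. At 5.76 M reads in genes per library, 20448 ± 206 gene models were detected at day 0 and 19771 ± 340 at day 14 (SD, n = 12 each), a difference of -677 (exact permutation test within cultivars, two-sided, p = 1.25e-05, the smallest it can give). Without the 6 libraries the difference was -620 (exact permutation test, p = 2.5e-05, again the smallest). At day 7, 19559 ± 1740 were detected (n = 12; exact permutation test against day 0, p = 0.0285), and 20293 ± 186 without the doubtful libraries (n = 8; p = 0.0524).

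Each library was placed on an axis from day 0, at 0, to day 14, at 1, made from the other cultivars. At day 7 the means were 0.172 ± 0.0891 in OP, 0.452 ± 0.218 in IS, 0.399 ± 0.0842 in GGI and 0.0795 ± 0.0752 in GQ (SD, n = 3 each), and at day 14 0.786, 0.842, 1.13 and 0.918. Over the cultivars, day 7 lay 0.276 above day 0 and day 14 lay 0.642 above day 7. Without the 6 libraries these were 0.280 and 0.616. Each day 0 library was measured against the other day 0 libraries of its cultivar, so the day 0 means are 0 by construction. Permutation tests of these positions kept the axis and the baseline of the real labels. Their p-values are therefore not exact and are not given. The hypothesis that the day 14 change may be under way at day 7 in every cultivar stays open: the day 7 mean lay above every day 0 library in 3 cultivars, while in GQ it lay above the day 0 mean and within the day 0 range, which reached 0.186. The gap in GQ is within the spread, and 2 of its 3 day 7 libraries are among those high in reads outside genes. In OP, the mean passed the day 0 range only through day 7 replicate 1, also high in such reads, at 0.274. Day 7 replicates 2 and 3 of OP lay at 0.108 and 0.135, below its highest day 0 library at 0.164.

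Later GGI libraries missed 13.1% to 16.7% of the 84 marker states of day 0, against at most 7.14% in OP and GQ and 4.76% in IS, over libraries outside the 6. A loss common to markers chosen on 3 libraries was argued against by that lowest GGI share of 13.1%. GGI plants of another genotype at the later days could not be tested, because 1 gene model switched in GGI against a state kept in at least 2 other cultivars, too few to decide. In GGI, 18 gene models were on in every day 0 library and off in every later one outside the 6, and 14 the reverse. These numbers were 3 and 7 in OP, 4 and 6 in IS and 2 and 5 in GQ. The later libraries used were 4 in GGI, 5 in OP, 6 in IS and 3 in GQ.

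Each tested gene model was paired with the next tested one in the order of the IDs, skipping those not tested. Their log2 fold changes at day 14 correlated across 21739 pairs with r = 0.105, above the range of -0.0146 to 0.0183 in 100 shuffles of the order. The hypothesis that tested gene models next to each other in ID order change together thus stays a candidate. Gene models are not independent replicates, and whether such gene models are neighbours on a chromosome was not tested.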
